A study of Mus musculus with 2 samples.

How the data were processed

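Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse liver (strain C57BL/6) with an antibody against the amino-terminal, nuclear domain of SREBP-2 and, as a control, with non-specific immunoglobulin (IgG). SREBP-2 is the transcription factor that activates genes of cholesterol synthesis and uptake when cell sterols are low. There is 1 sample per antibody, so neither antibody has replicates. Per the labels' protocols, 20 ng of immunoprecipitated DNA was made into an Illumina library after selection of fragments of 200 ± 5 bp, and both samples were sequenced on a Genome Analyzer.

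The authors deposited 1 file of aligned reads per sample, with the chromosome, start, end and strand of each read, and 1 list of SREBP-2 peak regions with their chromosome, start and end. The deposited read files also carry a score column, which holds the constant 1 on every line and was not used as a measurement. The peak list has no score, height or p-value. The aligner, the peak caller, its threshold and the genome build are not given in the sources used here. Starts were taken as 0-based, as in the BED format, and are printed 1-based. The SREBP-2 file holds 7312431 reads of 36 bases at 2396147 distinct positions (chromosome, 5' end and strand), or 3.05 reads per position. The IgG file holds 12762782 reads at 7011345 positions, or 1.82 per position. Identical reads had thus not been removed before deposit.

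The IgG reads have 2 lengths, 36 bases (75.1% of reads) and 37 bases (24.9%). Only 0.488% of the positions of the 37-base reads were also present among the 36-base reads. Of the SREBP-2 positions 0.786% were among the 36-base IgG reads, so the 2 IgG read lengths overlapped no more than separate libraries did. Of the 37-base positions only 44% held a single read. Together these values argue against 2 runs of 1 library, although no shift between the read lengths was tried. The IgG library below means all reads of this file. The 36-base and 37-base reads were therefore also used separately as controls, a choice made after the data were examined.

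The coordinates were compared with the only annotation at hand, a RefSeq gene table of GRCm38.p6. Reads reached past the last gene of that table on 10 chromosomes, by 7.2 Mb on chromosome 7, and stopped short of it on 11, so the builds differ. On all 20 chromosomes compared (the autosomes and X), no read lay beyond the end of the mouse build NCBI37/mm9, and the last read ended a median of 422 bases before it (3 to 31693). The mm9 lengths were supplied from general knowledge and not from the deposited data. Coordinates below are those of the deposited files and are taken to be mm9. No annotation or sequence of that build was used here, and coordinates were not converted. For this reason the planned tests of distance to transcription start sites, of sequence motifs and of 12 fixed gene lists could not be run, and peaks are named by position and not by gene. The 12 lists were cholesterol synthesis, sterol uptake and regulation, fatty acid and triglyceride synthesis, non-sterol isoprenoids, bile acids, autophagy, apoptosis, the unfolded protein response, glucose metabolism, abundant hepatocyte genes, ribosomal proteins and markers of non-parenchymal liver cells, and none has a result. The peak list used here has regions on 19 of the 21 chromosomes of the read files, and it may not be the whole of the authors' list. Chromosomes 19 and Y were not analysed here for peaks or for signal outside peaks.

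For counting, 1 read was kept per position and strand, and each read was placed at the estimated fragment centre by moving its 5' end 100 bp downstream, to the middle of a fragment of the stated 200 bp. Reads in each peak were divided by the number of distinct positions of the library. The ratio of SREBP-2 to IgG was computed with 1 read added to each count. The read was added before scaling and weighs more in the shallower SREBP-2 library. It therefore pulls ratios from few reads towards a value above 1. Its 95% interval is the exact Clopper-Pearson interval of the SREBP-2 share of the raw counts, turned into a ratio. A peak was counted as above IgG when the lower bound exceeded 1. These intervals cover counting error in these 2 libraries only, not the spread between animals, chromatin preparations or libraries. Amplified reads without molecular identifiers are not independent molecules. The peaks were presumably chosen on the same reads, so their ratios are a description and not independent evidence of binding.

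Mean profiles were counted in 25 bp steps within 2000 bp of the peak midpoints. The width of a profile was read at 50% of its height above the flanks. The centre was the inner 100 bp to each side and the flanks lay 1500 to 2000 bp away. Intervals of profile measures came from 2000 bootstrap resamples of the peaks, and the interval of the median ratio from 10000. Peaks per chromosome were compared with the distribution of distinct reads by a two-sided exact binomial test with Benjamini-Hochberg adjustment over the 19 chromosomes. The share of IgG positions in the peaks that were also SREBP-2 positions, at the best shift of up to 2 bp, was divided by the share that carried-over SREBP-2 reads would need, which is the excess over the flanks times the share of SREBP-2 reads in the peaks not alone at their position. Distances between peaks were compared with 10000 draws of read positions with the same number per chromosome. Outside the peaks, 200 bp windows with at least 10 SREBP-2 reads and a lower bound of the ratio above 3 were listed, and the same was done with the libraries exchanged. The peaks named were fixed by rule as the 20 with the highest ratio among those with at least 20 SREBP-2 reads. The rule and the main settings were chosen before the data were examined. The tests of chromosomes, of distances between peaks and of profile shape were added afterwards.

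The alternatives were all reads as deposited, scaling by 10 kb bins without peaks, windows of 250 bp to each side of the midpoint, reads at their 5' end or moved by 47 bp, 5 reads added, a lower bound of 2, at least 20 reads per window, IgG reads thinned at random to the number of distinct SREBP-2 reads (100 draws), neighbouring peaks counted once, and each IgG read length alone. The counting was tested on simulated data made by dividing the IgG reads at random. With no true difference, 37 of 1800 peaks had a lower bound above 1. A random division holds counting error only, so this count is not the rate of false calls between separately made libraries. When the shorter IgG reads were instead compared with the longer ones, 356 of the 1800 peaks had a lower bound above 1.  At 2 peaks the upper bound lay below 1. Of peaks given a true ratio of 2, 4 and 8, 22.1%, 89.4% and 98.5% were found. The simulated control held only the IgG reads left after the draw, fewer than the full library, which can lower these shares. The planted counts were drawn around the same control counts that entered the interval. The counting error of the control was thus left out, which can raise shares where most peaks were found. The net direction is not known. Outside peaks, 1 window was listed with no difference. Of windows with 4 to 8 control reads, drawn with peaks not excluded, 0%, 33.3% and 100% were found when planted at 4-fold, 8-fold and 16-fold. The windows listed in the real data held 1 to 3 IgG reads, so these rates do not describe them directly. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.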

Results

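SREBP-2 occupancy in mouse liver chromatin was measured by ChIP-seq in 1 SREBP-2 library, with 1 IgG file as the control. The SREBP-2 library held 2396147 distinct read positions and the IgG library 7011345. The peak list used here holds 1800 SREBP-2 peaks on 19 chromosomes, with a median width of 367.5 bp (114 to 1387 bp), that cover 725.5 kb. The question was where in the liver genome SREBP-2 is bound. As neither antibody was replicated, no difference below can be set against the spread between animals.

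SREBP-2 reads exceeded IgG reads in nearly all deposited peaks. At 1663 of the 1800 peaks (92.4%), the lower bound of the ratio lay above 1. The interval spanned 1 at the other 137, and no peak had an upper bound below 1. The median ratio over peaks was 3.15 (95% bootstrap interval 3.11 to 3.21), with 5th and 95th percentiles of 2.05 and 6.73. The ratio exceeded 5 at 252 peaks and 10 at 32. A lower bound above 2 was reached at 525 peaks. A lower bound above 1 also arose without the SREBP-2 antibody. With the shorter IgG reads compared with the longer ones, it was found at 356 of the 1800 peaks, and an upper bound below 1 at 2. A lower bound above 1 is therefore not by itself evidence of SREBP-2 binding. A typical peak rested on few reads, with medians of 21 SREBP-2 and 19 IgG reads, so a peak with a true ratio of 2 was often not distinguishable from 1 at this depth.

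The peaks together held 44465 SREBP-2 reads, or 1.86% of the library (exact 95% interval 1.84% to 1.87%). They held 38514 IgG reads, or 0.549% (0.544% to 0.555%). The ratio of these shares was 3.38 (3.33 to 3.43). The choice of control changed its size. Against the 36-base IgG reads alone the ratio of shares was 2.91, and against the 37-base reads alone it was 7.73. The median ratio over peaks was 2.74 and 5.42 in the same order. Lower bounds above 1 were found at 1491 and 1555 peaks, and at 1367 peaks against both. The 37-base reads were shallow in peaks, with a median of 2 reads per peak against 17 for the 36-base reads. The read added to each count therefore pulls ratios against the 37-base reads down, towards a value below 1.

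**Figure D1:**
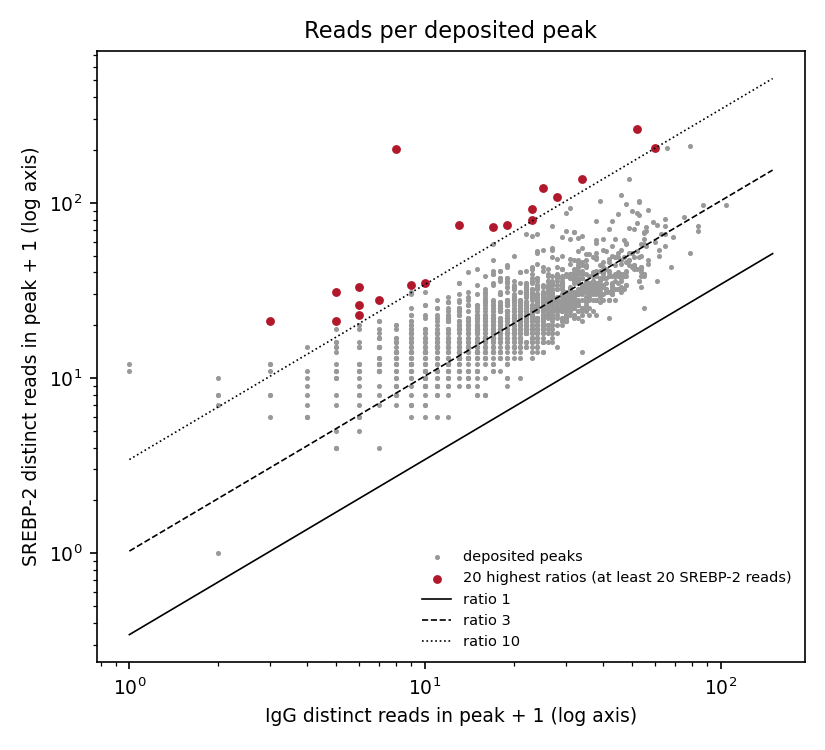
Distinct SREBP-2 reads (vertical, log axis, 1 added) against distinct IgG reads (horizontal, log axis, 1 added) in each of the 1800 deposited peaks, with lines at library-scaled ratios of 1, 3 and 10. With 1 read added, all points lie above the line at 1, including the peak with no SREBP-2 read and 1 IgG read, and the 20 peaks with the highest ratios among those with at least 20 SREBP-2 reads (red) lie near or above the line at 10. The added read is unscaled and can lift peaks with few reads above the line at 1. At the peak with no SREBP-2 read the interval of the ratio was 0 to 114.1.

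The shape of the read density differed between the antibodies. The peak midpoints were presumably set by the SREBP-2 reads, so a narrower and higher SREBP-2 profile is partly built in. SREBP-2 reads formed a narrow summit at the peaks, 275 bp wide at 50% of its height, and were 30.8 times as dense at the centre as in the flanks (95% bootstrap interval 27.2 to 34.0). IgG reads also rose at the same places. They were 7.65 times as dense at the centre (7.15 to 8.12), in a broader profile of 750 bp (750 bp for the 36-base and 450 bp for the 37-base reads). The 36-base IgG reads gave 8.40 (7.78 to 8.996), the 37-base reads 3.90 (3.28 to 4.44), and all IgG reads as deposited 4.88 (3.27 to 6.66). Plus-strand and minus-strand reads at the peaks were offset by 95 bp in the SREBP-2 library and by 85 bp in the IgG library, less than the stated fragment length of 200 bp. The shift of 100 bp used for counting is therefore larger than these offsets imply. Profile widths, centre-to-flank ratios and windows outside peaks were not repeated with the shift of 47 bp, so they depend on this setting. Of the 1012 peaks with at least 20 SREBP-2 reads, 93% had the minus-strand median downstream of the plus-strand median, by a median of 90 bp (25th to 75th percentile 58.5 to 113.1 bp).

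**Figure D2:**
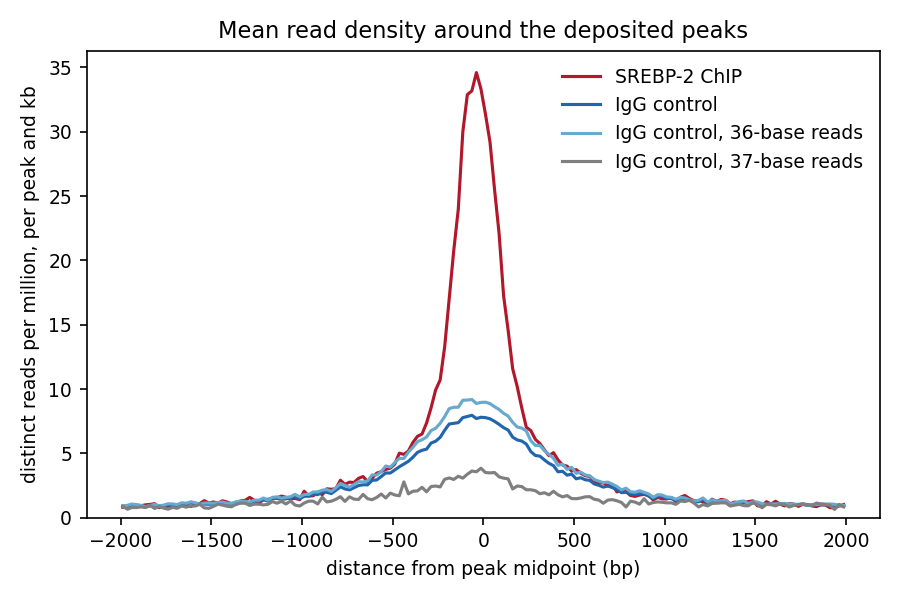
Mean density of distinct reads (vertical, scaled to 1000000 distinct reads of the library, per peak and kb) by distance from the midpoint of the 1800 deposited peaks (horizontal, bp), for the SREBP-2 library, the IgG library and the IgG reads of each length. The SREBP-2 curve reaches 34.6 in a narrow summit and the IgG curve 7.97 in a broader one, with the 36-base reads at 9.20 and the 37-base reads at 3.86. The SREBP-2 summit is not centred on the midpoint, with its highest step at -37.5 bp. It has 29.98 at -112.5 bp and 17.25 at 112.5 bp, where the IgG curve has 7.787 and 7.008. The cause of this skew was not tested.

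The peak with the most SREBP-2 reads lay on chromosome 8 at 67212235 to 67212797 (563 bp). It held 263 SREBP-2 and 51 IgG reads, a ratio of 14.9 with an interval of 11.1 to 20.8. On chromosome 5, the peak at 4104286 to 4105008 held 206 and 59 reads, with a ratio of 10.1 (7.62 to 13.9). A further peak on chromosome 5, at 125946123 to 125946548, held 120 and 24 reads (ratio 14.2, 9.38 to 23.7). At 44339307 to 44339650 on the same chromosome the ratio was 16.9 (9.74 to 36.5), from 74 and 12 reads. The peak on chromosome 15 at 59146231 to 59146790 had 136 and 33 reads and a ratio of 11.8 (8.19 to 18.2). On chromosome 9, a pair of named peaks lay 15.7 kb apart. The one at 42072206 to 42072636 had 107 and 27 reads (ratio 11.3, 7.55 to 18.4), and the one at 42087968 to 42088298 had 20 and 2 (ratio 20.5, 7.11 to 258).

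**Figure D3:**
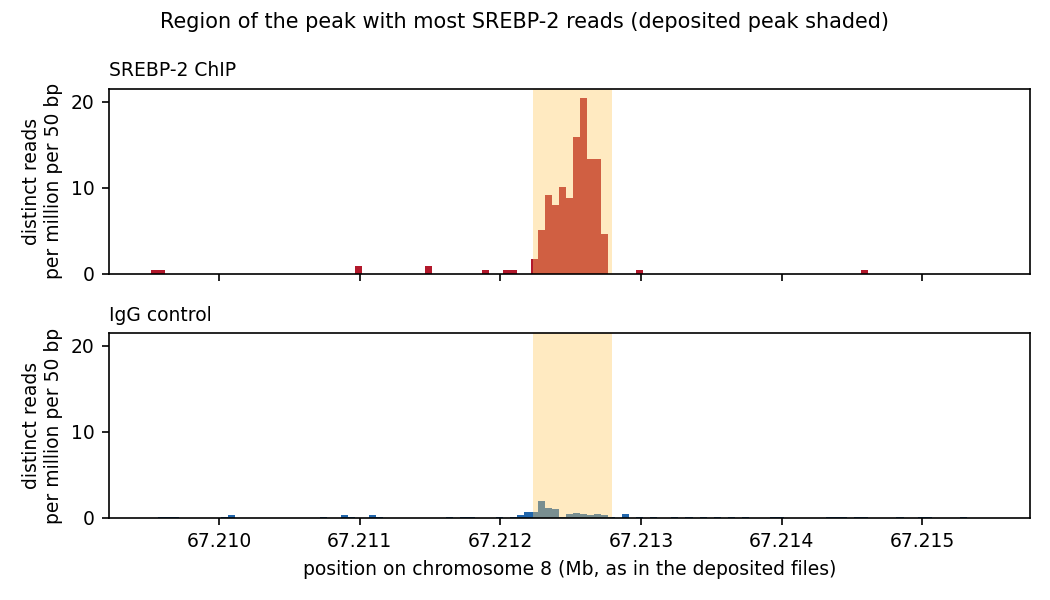
Distinct reads in 50 bp steps, scaled to 1000000 distinct reads of the library (vertical), along 3 kb to each side of the peak with the most SREBP-2 reads (horizontal, Mb on chromosome 8), in the SREBP-2 library (top) and the IgG library (bottom), with the deposited peak shaded. The highest step was 20.4 in the SREBP-2 library (from 67212566) and 2.0 in the IgG library (from 67212266), at different places. In the highest SREBP-2 step the IgG library had 0.428.

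The highest ratio in the list, 74.2 (40.2 to 213), belonged to the peak on chromosome 11 at 7099732 to 7099990, with 202 SREBP-2 and 7 IgG reads. Its SREBP-2 positions carried 8.68 reads each, where the 95th percentile of the peaks with at least 20 reads was 2.54. Its strands were offset by 26 bp. Many further named peaks also lay above that percentile. Values of 2.59 to 3.02 were found at 44339307, 4104286 and 125946123 on chromosome 5, and at 107115538 on chromosome 8. The same range held 23198339 on chromosome 6, 78534209 on chromosome 1 and the peak with the most SREBP-2 reads (2.62). The highest were 4.97 reads per position at 146700280 on chromosome 6 (strands offset by 198.5 bp) and 3.7 at 42087968 on chromosome 9. Of the other named peaks, the ratios on chromosome 14 were 16.1 at 58690861, 12.3 at 25598670 and 11.7 at 67487565. On chromosome 8 they were 12.6 at 107115538 and 10.2 at 13159085. On chromosome 6 they were 18.1 at 146700280 and 11.2 at 23198339, and on chromosome 1 they were 12.7 at 167932831 and 11.1 at 78534209. The remaining 3 named peaks were on chromosome 3 at 58496246 (11.7), chromosome 15 at 31383271 (11.6) and chromosome 17 at 31701605 (10.2). The lower bound was at least 4.76 at each of the 20 named peaks. Against the 36-base IgG reads 18 of the 20 were again among the highest 20, and against the 37-base reads 4 were. The 36-base reads supplied 34977 of the 38514 IgG positions in the peaks, so the first agreement is largely built in. The 37-base ranking rests on a median of 2 control reads per peak.

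Outside this rule, and chosen after their values were seen, 2 peaks held no IgG read. The one on chromosome 1 at 188529184 to 188529378 had 11 SREBP-2 reads and the one on chromosome 8 at 64533588 to 64533773 had 10. The lower bounds of their ratios were 7.34 and 6.56. The peak on chromosome 17 at 14108889 to 14109007 held no SREBP-2 read and 1 IgG read.

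In the peak list used here, peaks were not spread over the chromosomes as the reads were. That list may not be whole, and regions missing unevenly from it would change these counts. Chromosome X held 9 peaks where the distribution of IgG reads gave 34.4, or 0.261 times the expected number (exact binomial test, adjusted p = 8.39e-06). Chromosome 10 held 125 peaks where 95.2 were expected (1.31 times, exact binomial test, adjusted p = 0.025), and chromosome 17 held 105 where 79.7 were expected (1.32 times, adjusted p = 0.0314). The other 16 chromosomes did not pass the test. In the same exact test against the 36-base IgG reads, X (adjusted p = 9.84e-05) and 10 (0.0138) passed and 17 did not (0.0964). With the SREBP-2 reads outside the peaks as the reference 9 chromosomes passed, 5 with more peaks and 4 with fewer, and with the 37-base IgG reads also 5 and 4. Chromosome X passed with fewer peaks in each of the 4 cases. The test treats peaks as independent, but some are adjacent. With midpoints under 10 kb apart counted once (1680 groups) the same 3 chromosomes passed the exact test, X at 0.28 times the expected number (adjusted p = 5.24e-05), 10 at 1.29 times (adjusted p = 0.04) and 17 at 1.34 times (adjusted p = 0.0341).

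**Figure D4:**
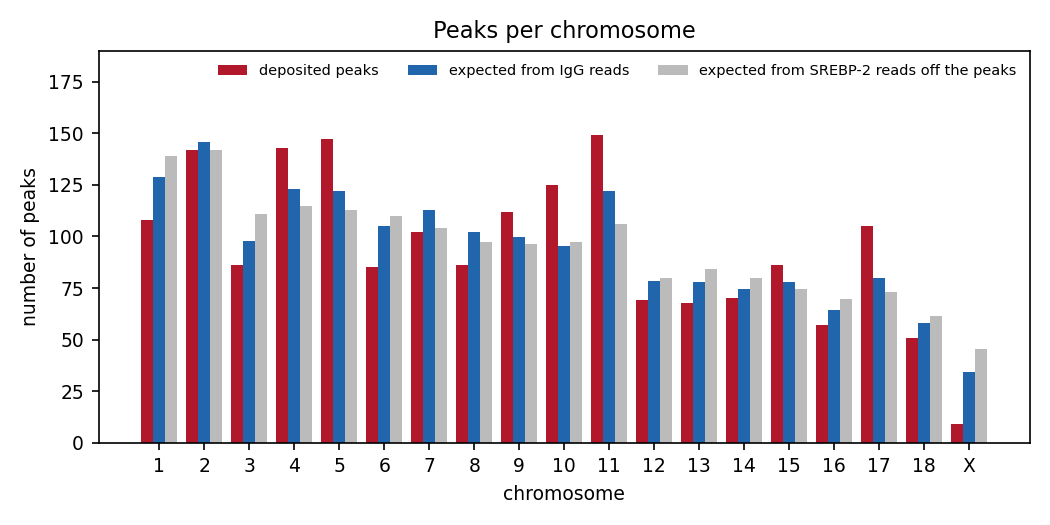
Number of deposited peaks on each of the 19 chromosomes with peaks (red), beside the numbers expected from the distribution of IgG reads (blue) and of SREBP-2 reads outside the peaks (grey). Chromosome X has 9 peaks where 34.4 and 45.4 were expected, and chromosome 10 has 125 where 95.2 and 97.2 were expected.

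Peaks also lay closer together than reads drawn at random. Another peak midpoint lay within 10 kb for 12.8% of the peaks, where draws of IgG reads gave 2.63% (95% of draws 1.67% to 3.72%; two-sided permutation p = 0.0002, the smallest that 10000 draws can give). There were 110 groups of at least 2 peaks with gaps of up to 10 kb, 9 of them with at least 3. The largest held 4 peaks on chromosome 1, from 107886848 to 107890754, with ratios of 2.73, 2.68, 2.41 and 4.63. Part of this closeness came from adjacent regions, since 149 peaks lay within 1 kb of another. With midpoints under 1 kb apart counted once, the share was 4.99% against 2.36% in the draws (permutation p = 0.0002, again the smallest possible).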

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

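The tests of the IgG profile with their alternatives, of positions shared with the SREBP-2 library and of the highest-ratio peak were chosen only after the results had been seen, as were the use of each IgG read length as a separate control and the thinning of the IgG reads. The other tests in this part were set down before their results.

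Whether SREBP-2 signal outside the deposited peaks exceeded the background of exchanged libraries depended on the setting. Outside the peaks, 19 windows of 200 bp (19 regions once adjacent windows were merged) held at least 10 SREBP-2 reads with a lower bound of the ratio above 3, against 10 windows (2 regions) with the libraries exchanged, while 217 windows of the same kind overlapped the peaks. With the IgG library thinned at random to the number of distinct SREBP-2 reads, a median of 3 windows passed (0 to 7 over 100 draws) against 10 exchanged (8 to 13), and a median of 3 regions (0 to 7) against 3 (1 to 5). With at least 20 reads required 0 windows passed against 10 exchanged (0 against 8 after thinning), against the 37-base IgG reads 6 against 27, against the 36-base reads 12 against 3, and with all reads as deposited, where copies of 1 fragment count as separate reads, 41513 against 1666. The strongest outside window lay on chromosome 13 at 4232801 to 4233000, with 12 SREBP-2 reads and 1 IgG read (ratio with 1 read added 19.02), too few to settle a single window. Its 12 distinct SREBP-2 reads stood for 53 reads as deposited, so many of those were copies.

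IgG reads were 7.65 times as dense at the centre of the SREBP-2 peaks as in the flanks, and 4.88 times (3.27 to 6.66) with all reads as deposited. A pile-up from only one of the 2 read lengths in the control is argued against, since the lower value, that of the 37-base reads, was still 3.90 (3.28 to 4.44). SREBP-2 reads carried into the control would have given an equally narrow summit, and this is argued against as the whole source by an IgG profile 2.73 times as wide (2.25 to 2.82; 2.31 to 2.82 for the 36-base reads alone). The width of the 37-base profile did not decide (1.64 times, 1.15 to 1.91), but only 5.04% of the 37-base positions in the peaks were also SREBP-2 positions, 0.0898 of the share that carry-over would need (0.074 to 0.11), which argues against it as the whole source there too. Better recovery of accessible chromatin with any antibody is a candidate explanation that stays open, and no biological explanation was tested.

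The peak on chromosome 11 at 7099732 stood apart in its ratio (74.2) and in its reads per position (8.68). A short template amplified during library preparation may account for it. That explanation stays open, because its strand offset of 26 bp lay at percentile 12 of the peaks with at least 20 reads, low, but above the 5th percentile that the test required. That percentile was -16.22 bp, a reversed order of strands that a short template read from both ends need not give. The test therefore decides little. No biological explanation was tested.

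SREBP-2 positions carried fewer reads each inside the peaks (2.02) than in the whole library (3.05), and IgG positions likewise (1.5 against 1.82). Read stacks in a few abnormal regions are argued against: without the highest 1% of 10 kb bins the share of the gap left was 1.0. Windows without peaks but with as many IgG reads as the peaks had 2.32 SREBP-2 reads per position, which closed 0.708 of the gap (0.639 to 0.783). This is consistent with a property of regions where control reads also gather, with or without SREBP-2. Base composition, which affects amplification, is a candidate cause that was not tested without the genome sequence.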

How the results depend on the processing

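The use of each IgG read length alone, the shift of 47 bp, the thinned IgG reads, leaving out the highest-ratio peak, and every alternative for chromosomes, distances between peaks and the IgG profile were chosen after seeing the data. The count of 1663 peaks above IgG stayed within 1.5 times (1491 to 1752) under the 7 alternatives that kept the bound of 1, and fell to 525 with a lower bound above 2. The ratio of the shares of reads in peaks, 3.38, was 2.71 with all reads as deposited, 2.91 against the 36-base IgG reads and 7.73 against the 37-base reads. It was 3.38 when scaled by bins off the peaks and 3.36 without the highest-ratio peak. The median ratio over peaks, 3.15, was 2.44 with all reads, 2.80 in windows of 250 bp to each side, 3.31 with reads at their 5' end, 3.27 with the shift of 47 bp, 2.74 against the 36-base and 5.42 against the 37-base IgG reads. Each of these ratios stayed above 1. The 19 windows outside peaks became 0 with at least 20 reads (10 with the libraries exchanged), 12 against the 36-base reads (3 exchanged) and 6 against the 37-base reads (27 exchanged). With IgG reads thinned to the number of distinct SREBP-2 reads they became 3 (10 exchanged), and 0 with at least 20 reads (8 exchanged). With all reads they became 41513 (1666 exchanged), since copies of 1 fragment then count as separate reads. The number of chromosomes with more or fewer peaks than expected, 3, was 9 with SREBP-2 reads outside the peaks as the reference, 9 with the 37-base and 2 with the 36-base IgG reads, and stayed 3 with midpoints under 1 kb or under 10 kb apart counted once. The IgG centre-to-flank ratio of 7.65 was 8.40 for the 36-base reads, 3.90 for the 37-base reads and 4.88 with all reads. For the other moved values the cause was not tested. The excess of neighbouring peaks, 4.86-fold over draws, kept its direction and its call at 2.19-fold within 50 kb, 5.85-fold against SREBP-2 reads and 2.12-fold with midpoints under 1 kb apart counted once. Tests of transcription start sites, motifs and gene lists, and their alternatives, were not run, for want of an annotation and sequence of the build. No paired analysis was possible because each group has 1 sample. Depth limits what single peaks show: the median peak held 21 SREBP-2 reads.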

Other observations

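The peaks were divided into 4 sets of 450 by their ratio. This comparison was chosen after the data were examined, and is given as values. In the lowest set (ratios 1.21 to 2.60) the SREBP-2 reads were 20.3 times as dense at the centre as in the flanks, with a width of 325 bp at 50% of the height. In the highest set (4.10 to 74.2) they were 44.8 times as dense and 275 bp wide. The strand offset had a median of 84.5 bp in the lowest set (25th to 75th percentile 48 to 114) and of 96 bp in the highest (71.2 to 112). The IgG profile went the other way, with a centre-to-flank ratio of 8.73 in the lowest set and 5.58 in the highest. The reads of both libraries in the peak enter the ratio that formed the sets, so the order of both centre-to-flank ratios is partly built in. The median peak held 24 IgG reads in the lowest set and 12 in the highest, with 19 and 22 SREBP-2 reads.

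The IgG reads of the 2 lengths differed in where they fell. The 36-base reads had 0.637% of their positions in the SREBP-2 peaks and the 37-base reads 0.24%, a ratio of 2.65. Compared with each other as if one were a treatment, their ratio had a lower bound above 1 at 356 of the 1800 peaks and an upper bound below 1 at 2. Chromosome X took 1.7% of the 36-base positions, 2.46% of the 37-base positions and 2.41% of the SREBP-2 positions. The low share of 37-base positions also among the 36-base reads (0.488%) argues against 2 runs of 1 library. The sources used here do not say how the control reads were combined.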
